A study of Mus musculus with 10 samples.

How the data were processed

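Testis RNA of 15 mice, pooled by group of 3, had been read on CodeLink Expression 1-channel arrays (Cy5), with 2 arrays for each of 5 pools, and the deposited table held the normalised intensity of 10012 probes on 10 arrays. Per the labels, the arrays were processed in parallel. The deposited intensity values were on a linear scale with a median of 1.00, and the sorted values of all 10 arrays were identical (largest difference 0), so the values had been quantile normalised across arrays. The scanner software, background correction, spot flags and the normalisation program are not given in the sources used here. Values were missing for 115 probes on every array, and 9897 entered the work. Gene symbols and chromosomes came from the platform table and a mouse gene table matched by gene identifier (8975 probes) or symbol. In all 8983 probes carried 1 symbol, 1 carried several and 1028 none. The genome build behind the platform table is not given in the sources used here, so no coordinates are printed.

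Intensities were turned to log2 after values below the 5th percentile (0.0364) were raised to it, and arrays were shifted to a common median. Probes in the lowest 25% by mean log2 value (mean intensity below 0.207) were left out, which left 7422 probes for 6573 genes. Grouping followed the labels: 1 control pool and 4 TSA pools at 2.5, 5, 7.5 and 10 h. The numbers of the duplicate arrays did not pair arrays across pools, since deviations of same-numbered arrays correlated between -0.187 and 0.14 over 10 pairs of pools.

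At each time a size rule without a p-value was used: an absolute log2 fold of at least 1 with both arrays of the TSA pool above, or below, both control arrays. Tests used limma 3.58.1 in R 4.3.3 on the 5 pool means, which left 3 residual degrees of freedom, with Benjamini-Hochberg adjustment over all tested probes and an adjusted p under 0.05 as the limit. TSA pools against control took the lone control pool to vary like the TSA pools, and the trend was a slope per hour with the control at 0 h. A pool is n = 1, and differences between the 3 animals of a pool were not measured. The control was killed at 10 h, so only the 10 h pool matched it in time. All limma and camera p-values are two-sided and from models fitted across all probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

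Before the data were examined, 32 gene lists were fixed, of which 30 had at least 5 measured genes. Blood and erythroid markers (4 measured: Alas2, Car2, Epb42 and Hba-a1) and epididymis markers (2 measured: Eppin and Gpx5) were not tested. Lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives, with 1 probe per gene. In each pool a list's median log2 fold was also placed among 10000 random lists of the same size matched on mean expression in 10 bins.

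Genes were named by a rule set before the data were examined. It took, at each time, up to 10 of the highest and 10 of the lowest folds that met the size rule, with 1 symbol and a mean intensity above 1.99, the median of the tested probes. It further took the 10 largest changes each way that passed each limma test, up to 4 members per list of largest mean fold and above that intensity, and 20 genes always, of which 10 were measured (not measured: Hdac4, Hdac7, Hdac8, Hdac9, Hdac10, Hdac11, Prm1, Prm2, Tnp2 and H1f0). Other genes are said in the text to have been picked after their values were seen.

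The methods were tested on simulated data of 7422 probes, drawn independently, with the control pool varying like the TSA pools. The size rule found 51 of 100 probes changed 2-fold and 100 of 100 changed 4-fold, and it called 20 of 7222 unchanged ones. The test of TSA pools against control found 90 and 100 of 100, and the trend 78 and 100 of 100, each calling 16 unchanged probes. With nothing changed they made 4 and 1 calls, and camera found 5 of 5 shifted lists and 0 others.

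Alternatives planned before the data were examined were quantile normalisation, no shift of the arrays, no filter, the lowest 50% left out, an offset on the log scale, no floor, arrays and pools left out, size rules of 1.5-fold and 3-fold, limma on the 10 arrays with and without a replicate block, the pool as a random block, eBayes with trend and robust on, the order of the pools with a term for TSA, an estimated correlation, fry, and the mean of all probes of a gene. Alternatives chosen after the data were seen were leaving out the probes of a liver list, keeping only probes above the median, and centring each array on probes of like ID number in 50 bins. Comparisons between TSA pools, further lists of liver (44 genes measured), kidney (5), pancreas (7), skeletal muscle (14), neurons (36) and homeobox and patterning regulators (46) were also written after the data were seen. For arrays no counting depth applies, and the number of arrays limits the precision.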

Results

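Gene expression was measured in the testis of BALB/c mice, 9 weeks old, after 1 subcutaneous injection of trichostatin A (TSA), a compound that inhibits histone deacetylases. The 15 mice formed 5 groups of 3. The control group received the carrier alone and was killed at 10 h, and the TSA groups received 60 µg per mouse and were killed at 2.5, 5, 7.5 or 10 h. RNA of the 3 mice of a group was pooled, and each pool was read on 2 CodeLink 1-channel arrays, which gave 10 arrays in all. The duplicate arrays were technical, so each group was represented by 1 pool (n = 1), and the number of arrays limited the precision of every value. Each array held values for 9897 of 10012 probes, with a median intensity of 1.00 and a range of 0.0004 to 249.5. Duplicate arrays correlated across the tested probes with r between 0.995 and 0.998. The standard deviation of a single array on the log2 scale ranged from 0.0934 in the 5 h pool to 0.163 in the 7.5 h pool. After the dimmest 25% were left out, 7422 probes were compared, of which 6660 carried a single gene symbol. Log2 folds at a time point are given with the standard error from the duplicate arrays of both pools, which holds no difference between animals.

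The first comparison asked which transcripts differed from the control 2.5 h after TSA. Insl5, which encodes an insulin-like peptide hormone (probe 1176, chromosome 4), was 2.85-fold higher in the 2.5 h pool, with a log2 fold of 1.51 ± 0.096. Zic2, a zinc finger regulator of neural development, was 2.58-fold higher (1.37 ± 0.027), and the collagen gene Col16a1 was 2.56-fold higher (1.36 ± 0.11). Zmynd8, which encodes a protein that binds modified histones, had a log2 fold of 1.27 ± 0.17, and the transcriptional co-regulator Ifrd1 one of 1.23 ± 0.20. Ghrl, the gene of the peptide hormone ghrelin, was higher by 1.21 ± 0.12, and Nop10, a component of small nucleolar ribonucleoproteins, by 1.09 ± 0.27. On the lower side stood 1700030J22Rik at -1.09 ± 0.74 and Fbxw7, which encodes the substrate receptor of a ubiquitin ligase, at -1.002 ± 0.85. The errors of these last genes were nearly as large as their folds, since their duplicate arrays lay apart. In all, 50 probes were at least 2-fold higher and 18 at least 2-fold lower in the 2.5 h pool with both arrays beyond both control arrays. The same rule met 0 to 5 probes (median 2) when duplicate arrays of the same pools were set against each other in 20 contrasts. These contrasts hold array noise alone and give no background for differences between animals. With an offset added before the logarithm, 18 probes in place of 68 met the rule. When values were centred on probes of like ID number, an alternative added after the data were seen, Ifrd1, Nop10, 1700030J22Rik and Fbxw7 stood at 0.92, 0.99, -0.95 and -0.86 and no longer met the 2-fold limit.

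At 5 h most of the probes that were over 4-fold higher belonged to transcripts that are abundant in liver. Serpina1b, which encodes an alpha-1-antitrypsin (probe 5685, chromosome 12), was 16.9-fold higher than in the control pool (4.08 ± 0.13), and the apolipoprotein genes Apoa2 and Apoc1 had log2 folds of 3.37 ± 0.01 and 1.47 ± 0.10. Cyp2f2, a cytochrome P450 gene, was higher by 2.13 ± 0.052, Cat, the gene of catalase, by 1.75 ± 0.022, and Rnase4 by 1.47 ± 0.056. At 7.5 h Serpina1b stood at 0.00043 ± 0.13 and Apoa2 at 0.086 ± 0.011. Apoa1, Ttr and Fabp1, picked after their values were seen, had intensities of 28.5, 19.0 and 32.9 at 5 h, against 0.0708, 0.0951 and 0.351 in the control pool. No folds are given for them, since the control values were dim. A list of liver transcripts written after the data were seen held 32 of the 90 probes that were higher at 5 h, and 23 of the 28 that were over 4-fold higher. Insl5 (1.47 ± 0.035), Zmynd8 (1.33 ± 0.17), Zic2 (1.30 ± 0.074) and Ghrl (1.23 ± 0.12) were again among the probes that met the size rule. Of the 25 probes that were lower, 1700029M20Rik at -1.31 ± 0.62 was the only one with a symbol bright enough to be named. Without the probes of the liver list, an alternative added after the data were seen, 83 probes in place of 115 met the rule, 58 of them higher and 25 lower. With an offset added before the logarithm, 66 probes met it.

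**Figure D1:**
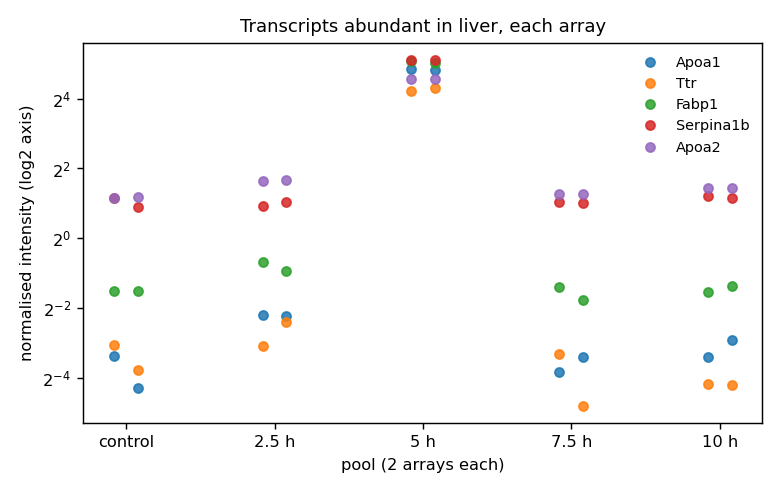
Normalised intensity (vertical log2 axis) of 5 transcripts that are abundant in liver, picked after their values were seen, on each of the 2 arrays of the control pool and of the 4 TSA pools (horizontal axis); each point is 1 array. Both arrays of the 5 h pool lie above all other arrays for every transcript shown, and mean Apoa1 intensity was 28.5 at 5 h against 0.0708 in the control pool.

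At 7.5 h Insl5 had the largest fold of the genes above the intensity limit for naming by time, at 1.74 ± 0.014, next to the homeobox gene Barx2 (probe 1942, chromosome 9) at 1.55 ± 0.041 and Ghrl at 1.51 ± 0.092. Ncan, which encodes the brain proteoglycan neurocan, was higher by 1.39 ± 0.21, and the potassium channel gene Kcnd2 by 1.12 ± 0.087. Col16a1 (1.36 ± 0.08), Zmynd8 (1.30 ± 0.19), Ifrd1 (1.19 ± 0.092), Ttyh2 (1.15 ± 0.066) and 1500002C15Rik (1.13 ± 0.05) completed the 10 named genes on the higher side. Hspa1l, a member of the Hsp70 family that is expressed in spermatids, was lower by -1.29 ± 0.08, and Nxn, the gene of nucleoredoxin, by -1.03 ± 0.15. The rule met 75 higher and 67 lower probes, and 30 higher and 7 lower with the lowest 50% of probes left out. The arrays of this pool differed most from each other, with 53 probes over 2-fold apart between duplicates against 9 to 15 in the other pools. With an offset added before the logarithm, 39 probes in place of 142 met the rule.

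The 10 h pool was the only TSA pool killed at the same hour as the control, and it held 91 higher and 107 lower probes. Insl5 was 3.49-fold higher (1.80 ± 0.11), and Zmynd8 was higher by 1.48 ± 0.18. Barx2 was higher by 1.40 ± 0.10 and Hoxb3, a homeobox gene of body axis patterning, by 1.21 ± 0.21. Bmpr1b, a receptor of bone morphogenetic proteins, stood at 1.19 ± 0.23 and Ttyh2 at 1.23 ± 0.17. Col16a1, Zic2, Ghrl and Ifrd1 were higher by 1.36, 1.30, 1.27 and 1.197. Tex101, a surface glycoprotein of germ cells (probe 2231, chromosome 7), was 2.3-fold below the control (-1.20 ± 0.036), while Tesk1, a protein kinase gene, stood at -1.41 ± 0.052. Sirt3, the gene of a mitochondrial deacetylase, was at -1.16 ± 0.14, the pyruvate kinase gene Pkm at -1.12 ± 0.041 and Nxn at -1.44 ± 0.15. Actr1a, which encodes a subunit of dynactin, was at -1.29 ± 0.073. Rassf1 stood at -1.21 ± 0.039, Abhd8 at -1.22 ± 0.021, Nubp2 at -1.21 ± 0.047 and Hspa1l at -1.11 ± 0.093. With an offset added before the logarithm, 71 probes in place of 198 met the rule. Ifrd1 stood at 0.91 after centring on probes of like ID number and no longer met the 2-fold limit.

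**Figure D2:**
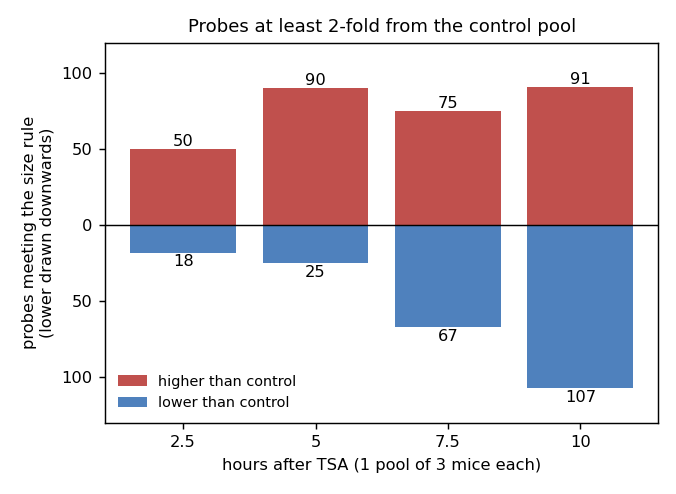
Number of probes at least 2-fold higher (upward bars) or lower (downward bars) than the control pool, with both arrays beyond both control arrays, against hours after TSA; each bar counts 7422 tested probes in 1 pool of 3 mice. Lower probes went from 18 at 2.5 h to 107 at 10 h, while higher probes numbered 50 to 91.

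The same rule met 20 probes on the higher side and 4 on the lower side at all 4 times, and 0 probes were higher at one time and lower at another. Insl5, Zic2, Zmynd8, Col16a1 and Ghrl were among the 20, and Cuzd1 and Pou6f1 among the 4. Zic2 stood at 0.92 at 7.5 h once values were centred on probes of like ID number, below the 2-fold limit. All 4 folds shared the control pool. When unchanged probes that share a control were simulated 100 times, a mean of 1.7 higher and 2.03 lower probes met the rule at all times. The highest numbers were 6 and 7. The simulation drew probes independently with the spread of the TSA pools, so a deviation of the control pool shared by many probes was not in it. The log2 folds of the 4 times correlated across probes with r between 0.69 and 0.85, against 0.50 in the simulation. Probes are not independent replicates. Contrasts between TSA pools were added after the data were seen. They gave 48 higher and 4 lower probes at 5 h than at 2.5 h, and 14 higher and 59 lower at 10 h than at 2.5 h. From 7.5 to 10 h there were 11 higher and 12 lower.

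Setting the 4 TSA pools, which came from separate animals, against the control pool asked which transcripts stood at a new level throughout. Insl5 rose 3.1-fold, with a log2 fold of 1.63 ± 0.16 (limma, adjusted p = 0.0390), and was higher in 4 of 4 TSA pools. Icosl, the ligand of a T cell costimulatory receptor, rose by 1.577 ± 0.12 (limma, adjusted p = 0.0122). Calcr, the calcitonin receptor gene, rose by 1.52 ± 0.19 (limma, adjusted p = 0.0400). Urgcp (probe 10719, chromosome 11) rose from an intensity of 0.102 in the control pool, too dim for an exact fold, to 1.36, 1.35, 2.13 and 1.504 at 2.5, 5, 7.5 and 10 h (limma, adjusted p = 0.00895). Prorsd1 rose by 1.72 ± 0.12 with the same adjusted p. S100a14 (1.69 ± 0.25), the small GTPase gene Rnd3 (1.48 ± 0.15), the homeobox gene Barx1 (1.44 ± 0.20) and Cyp2g1 (1.35 ± 0.16) also rose. Cox6a2, which encodes the muscle form of a cytochrome c oxidase subunit, rose by 1.37 ± 0.21. S100a14, Rnd3, Barx1, Cyp2g1 and Cox6a2 started from control intensities of 0.107 to 0.151, below the limit of 0.207 for mean intensity, so the sizes of their rises are uncertain. The same holds for Icosl and Calcr. Of the genes already named by time, Zmynd8, Zic2, Col16a1, Ghrl, Ifrd1, Nop10, Hoxb3 and Bmpr1b passed the test too, with limma adjusted p from 0.0338 to 0.0496. After centring on probes of like ID number the fold of Hoxb3 was 0.98 ± 0.18 and its adjusted p 0.0514.

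Among the transcripts with a gene symbol that fell, Cuzd1 (probe 5640, chromosome 7) fell most, to a log2 fold of -1.45 ± 0.18 (limma, adjusted p = 0.0400). The control was 2.74-fold above the TSA pools. The POU domain gene Pou6f1 fell to -1.20 ± 0.19, Slmap to -1.03 ± 0.14, and Cbll1, which encodes a ubiquitin ligase, to -1.01 ± 0.18. 4921524J17Rik (-0.97 ± 0.17), the signalling adaptor gene Tab1 (-0.96 ± 0.17) and Cnot9 (-0.91 ± 0.17), which encodes a subunit of a deadenylase complex, fell as well. So did the centrosomal gene Cspp1 (-0.91 ± 0.13), Apba3 (-0.89 ± 0.16) and Cpt1b (-0.81 ± 0.14), a gene of fatty acid entry into mitochondria. Each of these 10 was lower in 4 of 4 TSA pools, with limma adjusted p between 0.0400 and 0.0474. When values were centred on probes of like ID number, 6 of these 10 calls ended at adjusted p of 0.0514 to 0.0691. Their folds stayed on the lower side, at -1.04 ± 0.20 for Pou6f1, -0.87 ± 0.18 for Cbll1, -0.88 ± 0.19 for 4921524J17Rik, -0.85 ± 0.20 for Tab1, -0.79 ± 0.17 for Cnot9 and -0.79 ± 0.15 for Apba3. Slmap, Tab1 and Cnot9 were below an intensity of 0.207 in some TSA pools, so the sizes of their falls are uncertain. Brdt, the bromodomain gene of the testis, fell by 0.79 ± 0.15 on the log2 scale (limma, adjusted p = 0.0484). This call ended as well after centring, at -0.69 ± 0.14 (adjusted p = 0.0577).

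In total 262 probes passed the test of limma with Benjamini-Hochberg adjustment, 203 higher and 59 lower after TSA, and 38 of them changed at least 2-fold. At unadjusted p under 0.05 there were 2103 probes. Other planned fits gave other counts: 1 probe with no filter on dim probes, 0 with the order of the pools and a term for TSA (1497 at unadjusted p under 0.05), 573 with the lowest 50% left out, 795 with eBayes with trend and robust, and 1044, of which 467 were lower, with the pool as a random block. The test rests on 1 control pool, assumed to vary like the TSA pools, and single pools and arrays decided the count. It was 3 without the 2.5 h or the 5 h pool, and 6 and 7 without the 7.5 h or 10 h pool. Without the second array of every pool it was 1, without the first 27, and without the second control array 496. Single TSA arrays left out gave 5 to 180, with 5 without the second array at 2.5 h and 6 without the first at 7.5 h. Centring on probes of like ID number, an alternative added after the data were seen, gave 166 probes.

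**Figure D3:**
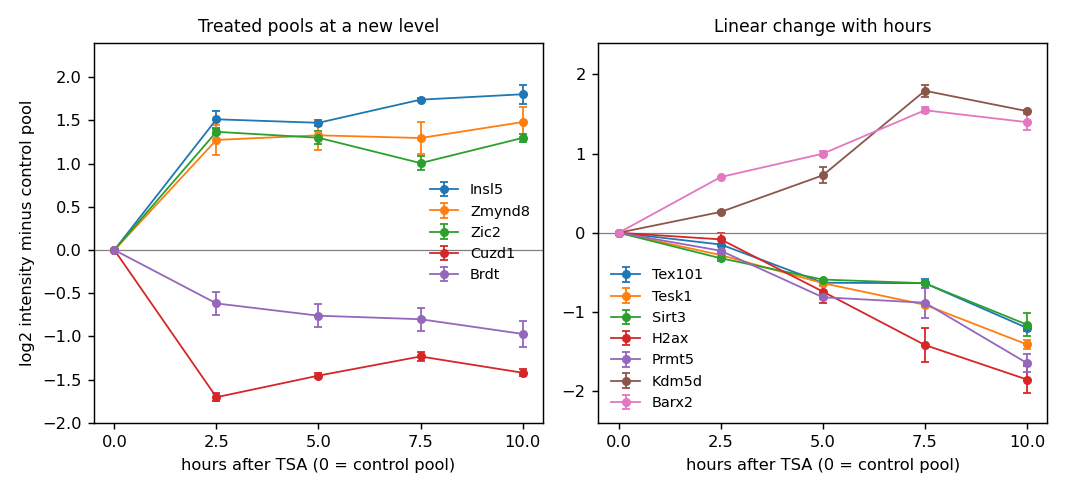
Log2 intensity minus that of the control pool (vertical axis) against hours after TSA (horizontal axis, 0 for the control pool, which was killed at 10 h) for 5 genes that passed the test of TSA pools against control (left) and 7 that passed the test of a linear trend (right); points are pool means and bars are standard errors from duplicate arrays. Insl5 stood at 1.51 at 2.5 h and 1.80 at 10 h, whereas H2ax went from -0.083 to -1.85.

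The linear trend over hours after TSA, with the control at 0 h, asked which transcripts changed linearly with hours. H2ax, which encodes the histone variant that is phosphorylated at DNA breaks (probe 1727, chromosome 9), fell with a slope of -0.202 ± 0.0199 log2 units per hour (limma, adjusted p = 0.0183). Its intensity at 10 h was 0.136, so the size of the fall is uncertain, as it is for Bop1, Sec61a1 and Ctu2, which were also below 0.207 at 10 h. Ppp5c, a protein phosphatase gene, fell at -0.198 ± 0.0207, the hormone-sensitive lipase gene Lipe at -0.185 ± 0.0148, and Bop1, a gene of ribosome assembly, at -0.18 ± 0.0181, all with the same limma adjusted p. Prmt5, an arginine methyltransferase gene with a role in germ cells, fell at -0.158 ± 0.0193 (limma, adjusted p = 0.0223), and Rpa2, a subunit of the protein that coats single-stranded DNA, at -0.171 ± 0.0196 (limma, adjusted p = 0.0185). Lmbr1l, Sec61a1, Fam110a and Ctu2 fell at -0.187 ± 0.0206, -0.175 ± 0.0252, -0.174 ± 0.0236 and -0.166 ± 0.0137. Of the transcripts that were lower at 10 h, Tex101 (-0.116 ± 0.0174), Tesk1 (-0.138 ± 0.0139), Sirt3 (-0.105 ± 0.0159), Pkm (-0.12 ± 0.0168), Nxn, Actr1a, Abhd8, Rassf1 and Nubp2 also passed the trend test, with limma adjusted p from 0.0183 to 0.0437. Hspa1l did not pass it (limma, adjusted p = 0.0647). The slope of Nubp2 was -0.0981 ± 0.0193 after centring on probes of like ID number, and its adjusted p 0.0517.

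Fewer transcripts rose with time. Kdm5d, the Y-linked gene of a histone H3 lysine demethylase (probe 9414), rose with a slope of 0.184 ± 0.0299 per hour (limma, adjusted p = 0.0437) and was 2.9-fold above the control at 10 h. Barx2 rose at 0.145 ± 0.0246, Ncan at 0.14 ± 0.0242 and Aplnr, the apelin receptor gene, at 0.148 ± 0.0266. Tirap, an adaptor of Toll-like receptors (0.141 ± 0.0259), Cd7 (0.124 ± 0.0226), Ly6d (0.102 ± 0.0167), Cldn15 (0.102 ± 0.0188), Ceacam14 (0.095 ± 0.0152) and Siglec1 (0.0947 ± 0.0173) rose too. Each of these was above the control in 4 of 4 TSA pools. Aplnr, Cd7 and Siglec1 started from control intensities of 0.108, 0.123 and 0.184, so the sizes of their rises are uncertain. After centring on probes of like ID number the slope of Cd7 was 0.115 ± 0.0224 and its adjusted p 0.0508. In total 149 probes passed the test of limma with Benjamini-Hochberg adjustment, 26 rising and 123 falling, and 78 of them changed at least 2-fold over 10 h. At unadjusted p under 0.05 there were 1866 probes, and 0 probes passed both this test and that of TSA pools against control. No filter on dim probes gave 0 (1863 at unadjusted p under 0.05), as did the order of the pools with a term for TSA (1251). The count was 289 with eBayes with trend and robust and 719, of which 273 rose, with the pool as a random block. Without the liver list, an alternative added after the data were seen, it was 243. The 123 falling probes had median log2 folds of -0.31, -0.58, -0.75 and -1.08 at 2.5, 5, 7.5 and 10 h. The count was 0 without the control pool, the 2.5 h pool or the 10 h pool (1251, 2126 and 1190 at unadjusted p under 0.05), 41 without the 5 h pool and 29 without the 7.5 h pool. Without the first or second array of every pool it was 24 and 60, and without the first or second array at 7.5 h it was 41 and 59. The fit without the control pool is the fit over the 4 TSA pools alone. The order of the pools with a term for TSA gives the same test, since the term takes up the control. Their counts of 0 probes, with 1251 at unadjusted p under 0.05, are thus the same result and not separate checks.

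Gene lists fixed before the data were examined gave a view by group. In both limma tests the count at unadjusted p under 0.05 over all 7422 probes, given above, far exceeded the 371.1 expected by chance. Counts at that limit within a list, and calls adjusted over a list alone, therefore do not by themselves set a list apart from other genes. The ribosomal protein genes were higher after TSA as a list of 57, with medians of 0.23, 0.099, 0.11 and 0.069 on the log2 scale at the 4 times. This was the only one of 30 lists to pass camera (adjusted p = 0.0285). The call was lost with an estimated correlation (adjusted p = 0.896) and when values were centred on probes of like ID number. Of its members, Rps7 rose by 0.65 ± 0.11 (limma, adjusted p = 0.0474) and Rpl22l1, picked after its values were seen, by 0.81 ± 0.12 (limma, adjusted p = 0.0449). The other 55 did not pass over all probes, and 7 passed adjusted over the list alone. Rpl30 (0.54 ± 0.11), Rpl29 (0.53 ± 0.13) and Rplp1 (0.58 ± 0.20) were among the 55. The 47 measured genes of the mitochondrial respiratory chain had medians of 0.24, 0.11, 0.16 and 0.13, at percentile 99.6 or higher of random lists in each pool, where all pools share the control. Ndufa5 (0.69 ± 0.12), Cox5b (0.62 ± 0.12) and Cox6a2 rose. Sdhc fell with time at -0.0841 ± 0.0149 per hour (limma, adjusted p = 0.0463), and Atp5b, at -0.51 ± 0.15, did not pass. The list itself did not pass camera (adjusted p = 0.111, and 0.896 with an estimated correlation), and 6 members passed adjusted over the list alone.

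Genes of histone acetylation, the process that TSA acts on, mostly stood below the control. The 12 histone acetyltransferases and acetyl readers had medians of -0.12, -0.13, -0.21 and -0.34, the last at percentile 0.3 of random lists. Besides Brdt, the acetyltransferase gene Kat5, picked after its values were seen, fell with time at -0.14 ± 0.0219 per hour (limma, adjusted p = 0.0421). Ncoa1 stood at 0.78 ± 0.24, Brd7 at -0.52 ± 0.12 and Brd3 at -0.37 ± 0.28 without passing. Adjusted over the list alone, 4 members passed against control and 5 with time, of which 1 was on the higher side in each test. The 10 histone deacetylase and sirtuin genes had medians of -0.20, -0.32, -0.23 and -0.22. Sirt3 fell with time, whereas Hdac1 (0.13 ± 0.13), Hdac2 (-0.047 ± 0.12), Hdac3 (-0.37 ± 0.12), Hdac5 (0.082 ± 0.16), Hdac6 (0.29 ± 0.18) and Sirt1 (-0.36 ± 0.14) did not pass either test. For this list 2 members passed against control and 1 with time adjusted over the list alone. Neither list passed camera (adjusted p = 0.425 for both against control). With time the smallest adjusted p of a list was 0.175, that of the acetyltransferases and readers (0.856 with an estimated correlation).

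Genes known to respond to deacetylase inhibitors in cultured cells were followed as a list. Of the 15 measured, 0 passed limma in either test over all probes and 0 adjusted over the list alone (3 against control and 1 with time at unadjusted p under 0.05). Their medians were 0.21, -0.0043, 0.13 and 0.036 at the 4 times, at percentiles 98.3, 57.3, 89.5 and 58.6 of random lists. Cdkn1a, the cell cycle inhibitor gene p21 that is often induced by such compounds, stood at 0.057 ± 0.17 (limma, adjusted p = 0.859). Cdkn1c stood at 0.42 ± 0.12, Gsn, the gene of gelsolin, at 0.36 ± 0.12, Klf2 at 0.36 ± 0.12 and Klf4 at 0.18 ± 0.15. Among p53 targets Trp53inp1 rose by 0.72 ± 0.12 (limma, adjusted p = 0.0474). Of 14, 2 passed against control and 1 with time adjusted over the list alone. Zmat3 (0.49 ± 0.11) and Mdm2 (0.30 ± 0.20) did not pass. Of 12 histone genes H2ax alone passed, over all probes and adjusted over the list alone. H2al2a (0.20 ± 0.12), H2az1 (-0.17 ± 0.12), H3f3b (0.16 ± 0.16) and Macroh2a1 (-0.46 ± 0.25) did not.

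Markers of meiotic spermatocytes had negative medians in every TSA pool. The 22 measured had medians of -0.10, -0.19, -0.16 and -0.33, at percentiles 9.4, 0.81, 1.95 and 0.02 of random lists of like expression. The list did not pass camera against control (adjusted p = 0.425) or with time (adjusted p = 0.522). Piwil1, a gene of the piRNA pathway (-0.61 ± 0.23), Spo11, which makes the breaks of meiotic recombination (-0.49 ± 0.17), Adam2 (-0.43 ± 0.12) and Pgk2 (-0.42 ± 0.13) did not pass singly. The X-linked gene Tex11, picked after its values were seen, rose by 0.88 ± 0.13 (limma, adjusted p = 0.0439). Adjusted over the list alone, 2 of 22 passed in each test, of which 1 rose against control and 0 rose with time. Of 23 markers of round spermatids Tcp11 fell with time at -0.105 ± 0.0138 per hour (limma, adjusted p = 0.0230). Acrv1 (0.55 ± 0.13), Adam5 (-0.58 ± 0.17) and Crem (-0.061 ± 0.12), the activator of spermatid genes, did not pass, and 3 of the 23 passed with time adjusted over the list alone. Of 17 markers of elongating spermatids 0 passed limma over all probes in either test, and 1 passed against control adjusted over the list alone (2 and 1 at unadjusted p under 0.05 against control and with time). Prm3 stood at 0.54 ± 0.11, Fscn3 at -0.43 ± 0.12, Ropn1 at 0.25 ± 0.12, Cabyr at -0.20 ± 0.14 and the transition protein gene Tnp1 at 0.20 ± 0.15. H1f6, the testis linker histone, stood at -0.17 ± 0.20. Of 9 spermatogonial markers 0 passed limma by either adjustment (3 and 1 at unadjusted p under 0.05). Stra8 stood at -0.31 ± 0.19, Dazl at -0.042 ± 0.17, Id4 at -0.059 ± 0.19 and Uchl1 at 0.0099 ± 0.11.

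Somatic cell markers showed no common direction. The 15 Sertoli cell markers had medians of -0.0056, 0.10, -0.079 and -0.012 at the 4 times. At 5 h Trf, a gene also on the liver list and picked after its values were seen, was higher by 2.19 ± 0.031. Ctsl (0.42 ± 0.11), Inha (-0.53 ± 0.20), Shbg (-0.48 ± 0.12) and Vim (0.44 ± 0.16) did not pass limma, and 3 of 15 passed with time adjusted over the list alone. The 12 Leydig cell and steroidogenesis genes had medians of 0.27, 0.12, -0.017 and 0.15, at percentiles 99.7, 92.5, 43.9 and 91.7. Star stood at -0.30 ± 0.35, Scarb1 at -0.49 ± 0.23, Sult1e1 at 0.24 ± 0.19 and Ptgds at 0.26 ± 0.12. In this list 0 passed limma over all probes (0 and 1 at unadjusted p under 0.05 against control and with time), and 1 passed with time adjusted over the list alone. Peritubular and smooth muscle genes had medians of 0.088, -0.26, -0.23 and 0.098. Acta2 stood at -0.35 ± 0.20, Dcn at 0.22 ± 0.17, Sparc at 0.20 ± 0.13 and Myh11 at -0.12 ± 0.16. Of these 12 genes 0 passed limma over all probes (2 and 3 at unadjusted p under 0.05), and 1 passed with time adjusted over the list alone. Macrophage and leukocyte genes had medians of -0.13, -0.35, -0.13 and -0.19. Fcgr3 stood at -0.41 ± 0.12, Cd74 at -0.41 ± 0.15, Ctss at 0.23 ± 0.15 and C1qb at -0.026 ± 0.16, and 0 of 12 passed limma by either adjustment (3 and 1 at unadjusted p under 0.05). Of 9 endothelial genes Cldn5, picked after its values were seen, fell with time at -0.125 ± 0.0217 per hour (limma, adjusted p = 0.0437), to a dim intensity of 0.119 at 10 h. Sox17 stood at -0.33 ± 0.13, and 1 of 9 passed in each test adjusted over the list alone. In the adipose list, with medians of 0.023, 0.34, 0.16 and 0.20, Adipoq (0.31 ± 0.17), Scd1 (0.55 ± 0.15) and Dgat2 (-0.54 ± 0.16) did not pass over all probes. Here 3 of 8 passed in each test adjusted over the list alone.

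In each of the cell cycle lists 1 gene passed with time over all probes. In the G1 and S list Mcm7, a subunit of the replicative helicase picked after its values were seen, fell at -0.124 ± 0.0139 per hour (limma, adjusted p = 0.0183). Cdk4 (0.44 ± 0.12), Pcna (-0.28 ± 0.15), Ccnd3 (-0.32 ± 0.17) and Cdk2 (-0.26 ± 0.10) did not pass. In the G2 and M list the mitotic kinase gene Plk1, also picked after its values were seen, fell at -0.101 ± 0.0173 (limma, adjusted p = 0.0437). Aurka (-0.57 ± 0.16), Mad2l1 (-0.41 ± 0.14), Bub3 (-0.37 ± 0.14) and Cdc20 (-0.34 ± 0.17) did not pass. In each of these lists 3 members passed with time adjusted over the list alone, and 1 of the 3 in the G1 and S list rose. Of 23 DNA repair genes Rad23b, picked after its values were seen, fell by 0.69 ± 0.12 on the log2 scale (limma, adjusted p = 0.0474). Nbn, Atr, Lig3 and Apex1 stood at -0.37 ± 0.16, -0.33 ± 0.12, -0.32 ± 0.11 and 0.24 ± 0.14, and 1 passed against control adjusted over the list alone. In the proteasome list Psmb5 rose by 0.56 ± 0.11 (limma, adjusted p = 0.0485) and Psmd13 fell with time at -0.077 ± 0.0129 (limma, adjusted p = 0.0437). Psmd2 (-0.55 ± 0.14) and Psma4 (-0.49 ± 0.19) did not pass. Adjusted over the list alone, 0 of 38 passed against control, so Psmb5 did not, and 2 passed with time. Of 24 apoptosis genes Diablo fell with time at -0.0842 ± 0.0144 per hour (limma, adjusted p = 0.0437). Aifm1, Cycs and Casp6 stood at 0.55 ± 0.12, 0.26 ± 0.12 and 0.22 ± 0.13, and 2 passed against control and 1 with time adjusted over the list alone.

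In energy and stress metabolism, Gapdh rose by 0.55 ± 0.11 (limma, adjusted p = 0.0485). Pkm fell with time, and so did Aldoc, picked after its values were seen, at -0.0989 ± 0.0136 per hour (limma, adjusted p = 0.0279). Eno3 stood at -0.25 ± 0.14. Of 18 glycolysis and sugar transport genes 1 passed against control and 3 with time adjusted over the list alone. After centring on probes of like ID number, Gapdh stood at 0.41 ± 0.10, Psmb5 at 0.48 ± 0.11, Rps7 at 0.57 ± 0.11 and Cox5b at 0.45 ± 0.11, and these calls ended at adjusted p of 0.0514 to 0.0795. The 27 genes of oxidative stress and detoxification had medians of 0.21, 0.12, 0.036 and 0.098, and Cat was high at 5 h together with the liver transcripts. Gsta4 (0.52 ± 0.11), Gstp1 (0.53 ± 0.17) and Prdx4 (0.46 ± 0.13) did not pass. In all 0 of 27 passed limma over all probes (6 and 3 at unadjusted p under 0.05 against control and with time), and 1 passed with time adjusted over the list alone.

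The inflammation and interferon list had medians of 0.0026, 0.30, 0.17 and 0.16. At 5 h Saa1, an acute phase gene of liver picked after its values were seen, was higher by 1.23 ± 0.12. Of its 14 genes 0 passed limma over all probes (7 and 6 at unadjusted p under 0.05), and 3 against control and 5 with time passed adjusted over the list alone. Stat3 stood at -0.39 ± 0.13, Ccl4 at 0.25 ± 0.15 and Nfkbia at -0.13 ± 0.17. In the clock list Arntl, picked after its values were seen, rose by 0.78 ± 0.14 (limma, adjusted p = 0.0474). Dbp stood at -0.063 ± 0.36, Clock at 0.073 ± 0.16 and Rora at -0.039 ± 0.14, and 1 of 11 passed against control adjusted over the list alone. In the cholesterol list Mvk, picked after its values were seen, fell with time at -0.084 ± 0.0153 (limma, adjusted p = 0.0484). Fdft1 stood at 0.49 ± 0.12, Nsdhl at -0.42 ± 0.11, Dhcr7 at 0.38 ± 0.15 and Ebp at -0.16 ± 0.16. In this list 3 of 11 passed against control and 2 with time adjusted over the list alone. Of 27 heat shock genes 0 passed limma by either adjustment (9 and 3 at unadjusted p under 0.05). Dnaja1 stood at 0.50 ± 0.12, Hspa4l at -0.53 ± 0.14, Hsp90b1 at -0.37 ± 0.11 and Hsp90aa1 at -0.33 ± 0.11. Of 13 immediate early genes 0 passed limma by either adjustment (2 and 5 at unadjusted p under 0.05). Jund stood at 0.35 ± 0.11, Dusp1 at 0.22 ± 0.15 and Ccn2 at -0.17 ± 0.22. Of 15 glucocorticoid and stress genes 0 passed limma by either (3 and 1 at unadjusted p under 0.05). Tsc22d3 stood at 0.30 ± 0.16, Errfi1 at -0.29 ± 0.16 and Klf13 at 0.23 ± 0.20.

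**Figure D4:**
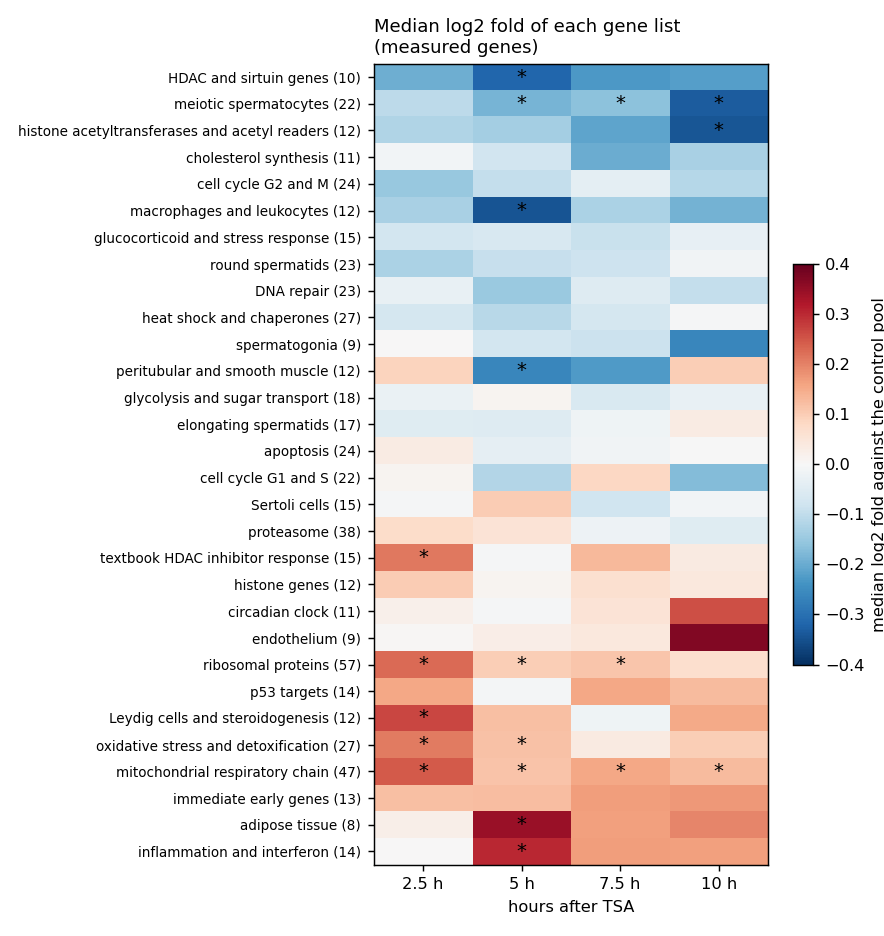
Median log2 fold against the control pool (colour scale) of the measured genes of 30 lists (vertical axis, number of genes in brackets) in the TSA pools at 2.5, 5, 7.5 and 10 h (horizontal axis); asterisks mark medians among the lowest or the highest 2.5% of random lists matched in size and expression. Of 120 medians 20 carry an asterisk. The 4 times share 1 control pool and random lists leave out the correlation between members of a list, so the asterisks are not independent.

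Against control, camera passed 1 of 30 lists with Benjamini-Hochberg adjustment and 2 at unadjusted p under 0.05, and with time it passed 0, with 2 at unadjusted p under 0.05. With an estimated correlation 0 lists passed in either test. Many of all tested probes had unadjusted p under 0.05 in both limma tests. The test fry compares no list with other genes, so its passes for changes in either direction do not set a list apart. Its first form asks whether the genes of a list move one way on balance. It passed 0 lists in either test (smallest adjusted p 0.301 and 0.0601). For changes in either direction within a list, fry passed 20 lists against control and 17 with time. The list count against control was 0 without the first array of every pool, without the first control array, without the first array at 2.5 h or without the 2.5 h pool, and 2 without the 10 h pool.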

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

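The tests of a lasting induction of liver genes, of which pool stood apart from the other pools, and of the hour and the order of killing were chosen only after the results were seen, and the liver list was also written after them. Among the 184 genes that the naming rule covers and that were tested, 11 had values on both sides of the control: both arrays of one TSA pool lay above, and both arrays of another lay below, both control arrays; the differences between the times were not tested, and duplicate arrays are technical. Log2 folds of Cdkn1a were 0.28 at 2.5 h and -0.11 at 5 h. Crem stood at -0.088 at 7.5 h and 0.052 at 10 h. Hdac5 was at 0.21 at 2.5 h and -0.14 at 10 h. Dazl had 0.16 at 2.5 h and -0.30 at 10 h, and Id4 had 0.25 and -0.21 at these times. Star showed -0.90 at 7.5 h and 0.15 at 10 h. Myh11 gave 0.083 at 2.5 h and -0.28 at 5 h. Ccn2 was at -0.39 at 2.5 h and 0.17 at 10 h, Dbp at -0.51 and 0.48, and Nfkbia at -0.33 and 0.088. Clock stood at -0.12 at 5 h and 0.26 at 10 h.

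Transcripts abundant in liver were high in the 5 h pool alone: of 44 measured liver genes 29 were at least 2-fold above the mean of the other pools. An error of 1 array is argued against, since both arrays showed the rise in 100% of these genes, and so is a lasting induction by TSA, since the genes high at 5 h, with a median log2 fold of 2.85 there, had one of 0.0847 at 7.5 h. RNA of liver in the 5 h pool may account for it. Among liver genes not marked as seen before the list was written, 30% (6 of 20) were at least 2-fold higher. Apoc1, 1 of these 6, had been named at 5 h by the naming rule, so it was not truly unseen. Of the unseen genes of kidney (5), pancreas (5) and muscle (12), 0 were at least 2-fold higher. The liver genes left unmarked were those without the highest values, so this share cannot decide. Of the 44 liver genes 9 were also above the naming intensity in the other pools. A brief induction that had ended by 7.5 h stays open as the biological explanation and was not tested.

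The control pool stood apart from all 4 TSA pools: it gave 262 probes as the odd pool of 5, and the highest count of another pool was 26, at 5 h; this was 1 of 5 splits, too few for a share under 0.05. The hour of killing is argued against as the only cause. The 10 h pool was killed at the hour of the control, yet it differed from the control in 198 probes by the size rule. It differed from the other TSA pools in 23 to 73. Folds drifted with the ID number of the probe, which may reflect the place on the array. Probes with ID numbers up to 2000 had a median log2 fold of 0.127 (quartiles -0.0996 and 0.365). The others had a median of -0.038 (quartiles -0.25 and 0.171). Calls on the higher side were more frequent among ID numbers up to 2000 than among the others. Centring on like ID numbers ended a larger share of the lower calls than of the higher ones. Centring on probes of like ID number ended 43.5% of the calls (114 of 262): the median fold of those 114 went from 0.699 to 0.595 on the log2 scale and its standard error from 0.127 to 0.123, so these calls lay near the limit of adjusted p and ended at adjusted p of up to 0.1005, while 166 probes passed. An effect of TSA and a difference of the single control pool cannot be told apart here, since there was 1 control pool.

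In 123 of 149 trend calls transcripts fell with hours after TSA, by slope and not always at each step. Of 60 orders of the pools, 1 gave as many probes, the real one with 149, and the highest of the others gave 0. This cannot exclude chance, since there was 1 pool per time and the probes of a pool share any deviation of that pool. The count was also 0 without the control, the 2.5 h or the 10 h pool. A shift shared by all genes of like length is argued against, as centring ended 12.7% of the falling calls with a length (14 of 110). Their median slope moved from -0.105 to -0.103. A shift shared by all probes of like intensity is argued against too, as centring ended 2.44% (3 of 123). Centring removes only such shared shifts, so it cannot decide whether short genes or dim probes fell more often. The falling genes had a median genomic length of 13.2 kb, against 20.3 kb for the others. The falling probes were dimmer, with a median mean log2 intensity of -0.22 against 1.03 for the others. The order of killing is argued against as the only cause. By the size rule the 10 h pool, killed at the hour of the control, had 107 probes lower than the control. The 2.5 h pool had 18. The pools at 2.5, 5 and 7.5 h differed from the control in both TSA and the hour of killing. A change with time after TSA stays open as the biological explanation, and the order in which pools were handled is not given in the sources used here and was not tested.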

How the results depend on the processing

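Alternatives chosen only after the results were seen were centring on probes of like ID number, leaving out the liver list, and keeping only probes above the median; the others were planned. With no filter the size rule met 219, 355, 554 and 458 probes at 2.5, 5, 7.5 and 10 h, limma passed 1 probe against control and 0 with time as more dim probes were tested, and 2 lists passed against control. With the lowest 50% left out it met 16, 27, 37 and 73, and 573 passed against control. With the offset it met 18, 66, 39 and 71, with the 1.5-fold rule 562, 730, 876 and 1221, and with the 3-fold rule 12, 42, 16 and 29. Treating the pool as a random block on 10 arrays gave 1044 against control and 719 with time (consensus correlations 0.599 and 0.626), and eBayes with trend and robust gave 795 and 289. Fitting the order of the pools with a term for TSA gave 0 and 0 in limma (1497 and 1251 at unadjusted p under 0.05). An estimated correlation and fry each passed 0 lists against control. Centring on like ID numbers gave 166 probes and 0 lists against control, and 34 in place of 20 list medians outside the random range. Without the liver list 243 passed with time, and with only probes above the median 452 against control. Leaving out arrays or pools gave 1 to 496 probes against control, 0 to 193 with time, 0 to 2 lists against control and 0 to 1 with time, the 1 when the control pool was left out. Size rule counts with arrays left out ranged 68 to 88, 115 to 128, 142 to 201 and 198 to 271. These ranges say little on stability, since the rule is looser with fewer arrays and arrays of other pools do not enter it. With a replicate block limma on the arrays gave 64, 114, 140 and 197 probes, against 63, 115, 139 and 197 without. Those 2 fits took the technical duplicates as replicates, so their p-values hold array noise alone and no difference between animals. The fit with the pool as a random block also counted arrays in its degrees of freedom, so its larger counts are no sign of stability. Quantile normalisation and no shift moved values by at most 0.00667 and 0, so they tested nothing, as did no floor. Of values of named genes at a time point 966 kept their call and 22 lost it. The numbers were 283 and 221 against control, and 319 and 205 for slopes, and 0 of all these changed side. Of values of genes named from lists or always, 2796 kept side and outcome, 116 gained a call, 112 lost it and 42, without a call, changed side. Of values of gene lists, 1487 kept side and outcome, 2 gained a call, 7 lost it and 90, without a call, changed side. Other causes were not tested. Signal over background could not be had, since backgrounds are not given in the sources used here.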

Other observations

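The tests of genes of other tissues used lists written after single genes had been seen. All lists below were chosen only after the results were seen. Genes marked as seen before were left out of the tests. Hoxb3, named at 10 h by the naming rule, was not so marked and stayed in, and no test was run without it. Homeobox and patterning regulators, which lay out the body axis and organs of the embryo, passed as a group on the higher side (camera p = 0.000156), a call that was lost with an estimated correlation (p = 0.226). The 40 measured genes not marked as seen, Hoxb3 included, had median log2 folds of 0.12, 0.15, 0.32 and 0.35 at 2.5, 5, 7.5 and 10 h. These lay at percentiles 98.6, 99.6, 100 and 100 of random lists. Of these 40 genes 31 stood above the control on average, and 5 rose (limma over all probes): Hoxb3 by 0.93 ± 0.18 (adjusted p = 0.0496), Hoxb13 by 0.74 ± 0.14 (adjusted p = 0.0485), Vax2 by 0.92 ± 0.18 (adjusted p = 0.0484), Evx1 by 1.00 ± 0.18 (adjusted p = 0.0474) and Gsc by 0.59 ± 0.11 (adjusted p = 0.0478). After centring on probes of like ID number these folds were 0.98 ± 0.18, 0.65 ± 0.13, 0.80 ± 0.18, 0.86 ± 0.17 and 0.41 ± 0.097, at adjusted p of 0.0514 to 0.0744, so all 5 calls ended, while the median fold of the list was 0.21 before and 0.25 after. Among the genes seen before, Hoxd1 rose by 1.14 ± 0.15, Hoxb5 by 0.83 ± 0.12 and Pax3 by 0.80 ± 0.11 (limma, adjusted p from 0.04 to 0.0439).

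Neuronal genes were a second group. The 30 unseen genes had median log2 folds of -0.011, 0.017, 0.081 and 0.19 at 2.5, 5, 7.5 and 10 h, and 2 of them rose (limma over all probes): the calcium channel gene Cacna1b by 0.75 ± 0.13 and Cplx2, a regulator of transmitter release, by 0.67 ± 0.13. After centring on probes of like ID number Cplx2 stood at 0.50 ± 0.11 with adjusted p 0.0665, so its call ended. Of the genes seen before, Gabrr1 rose by 1.02 ± 0.14 (limma, adjusted p = 0.0434), from a control intensity of 0.142 that leaves the size of the rise uncertain.

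A hypothesis is that TSA raised transcripts of genes that act mainly in other tissues. For homeobox and patterning genes the test was consistent with this as a group (camera p = 0.000156, direction up, and 9.2e-05 after centring on probes of like ID number), but not with an estimated correlation (p = 0.226). For neuronal genes the test did not pass (camera p = 0.0819, and 0.608 with an estimated correlation), so a rise of that group was not shown. These lists do not stand for silent genes, since 10 of the 40 homeobox genes and 5 of the 30 neuronal genes were above the naming intensity in the pools other than 5 h, and 12 of the 40 had ID numbers up to 2000, where folds ran higher. All TSA pools were set against the same single control pool, so an effect of TSA and a deviation of that pool cannot be told apart. No further biological explanation was tested.

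The probe with ID number 2712 (probe_2712), which has no gene symbol, is given as a value without explanation. Its mean intensity was 12.8 in the control pool and 0.0701, 0.162, 0.721 and 0.101 in the TSA pools at 2.5, 5, 7.5 and 10 h, and it fell in the test of TSA pools against control (limma, adjusted p = 0.0474).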
